A study of unidentified microorganism with 9 samples.

How the data were processed

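The series profiled microbial communities of acid mine drainage, the acidic and metal-rich water that leaves mined rock, at 2 locations, Dexing and Yingshankang. Per the labels' protocols, 23 water samples of 150 L each were filtered through a pore size of 0.2 µm, and genomic DNA from the filters was labelled with Cy3. It was hybridised to an array of probes for 16S rRNA genes, which identify organisms, and for functional genes. GEO lists 9 samples, each a numbered site, with 6 sites at Dexing (15 arrays) and 3 at Yingshankang (8 arrays). The 23 arrays equal the 23 water samples in number, but the labels do not tie a water sample to an array. Tests over the arrays of a site therefore measure only the spread between arrays, which may be technical.

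The deposited files are scanner output with 1 row per spot, written by GenePix Pro 6.0.0.45 on a GenePix 4100A scanner at 532 nm and a detector gain of 600, per the file headers. Laser power ran from 1.79 to 3.85. The foreground and background values are fluorescence intensity on a linear scale, not normalized, per the file headers. The deposited signal-to-noise value of each spot is a score, which was recomputed as foreground mean minus background mean over background SD and differed by a median of at most 0.00026 on any array. A column of saturated pixels gives a percent, per the file headers, and 9 spots over all arrays had more than 20% saturated pixels. Some spot names contain line breaks inside quotes, so the files were read with a quote-aware reader, and the range of every column was checked.

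Each array held 4608 spots in 1 layout. Of these, 128 were named as controls and 4480 belonged to 1120 probes of 4 spots each. The labels state 1072 probes (571 for 16S rRNA, 501 functional) and 320 control spots already removed, which the files do not match, and which of the 1120 probes the labels leave out is unknown. By name, 524 probes were 16S, 470 began with FGA, 68 began with GR and 58 had other names. The labels explain neither FGA nor GR. FGA probes were assumed to be the functional probes, as the largest class not named 16S. Whether GR probes, some of them named GRFGA, belong with them is unknown. The files pair most probes with sequence record numbers, but not some of those with other names, such as gy00615 and G26. They give no gene or organism names, except for 7 probes. Of 20 keyword lists for organisms and functions written beforehand, only the list of all 16S probes (524) had 5 or more members. The list of common heterotrophs or possible contaminants and the list of DNA replication and repair matched 1 probe each, and the other lists matched 0. The list for Acidiphilium and relatives missed a probe spelled acidiphillium sp 5. The functional categories of the series were therefore not analysed here.

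Intensities were corrected with limma 3.58.1 in R 4.3.3 by normexp with an offset of 50, quantile normalized between the 23 arrays after control spots were removed, and put on the log2 scale. The 4 spots of a probe were averaged. A probe counted as detected on an array when at least 2 of its 4 spots reached a signal-to-noise value of 2, and at a site when detected on at least 50% of the site's arrays. That asks for 1 array at sites with 2 arrays, but for 2 at sites with 3 or 4. Counts of called probes at sites therefore also depend on the number of arrays. Probes detected at 2 or more sites were tested. The design written beforehand called for unflagged spots only. The only flag in the files marks spots where the software found no feature, and it covers between 75.6% and 98.2% of the probe spots of an array. Leaving these out would remove low values and keep high ones, so they were kept, and the fit without them was run as an added alternative. The number of arrays limits the precision of every value, and most probes lay near background.

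Site means were compared between locations with limma (6 against 3 sites, Benjamini-Hochberg adjustment), and the 23 arrays between the 9 sites with limma's F-test. The 16S list was tested with camera at a preset correlation of 0.01, with fry beside it. Where a probe was below detection on every array of a location, or on most arrays of the sites compared with a single site, the fold is taken against the lowest detected signal of each undetecting array. The higher side enters at its own values. The fold is thus a lower bound of the estimate only where every array of that side detected the probe, and it leaves out sampling error. Detected probes, the Shannon index (natural log), Pielou evenness and shares of background-subtracted signal were averaged per site and compared by two-sided exact permutation tests over all 84 splits of the 9 sites, whose smallest possible p is 0.0119. The share of squared Bray-Curtis distances between sites that location accounts for (R2) was tested over the same 84 splits, and profiles of sites were compared by permutation of arrays among sites (100000 permutations). Distances from 16S and FGA probes were compared by a Mantel test (100000 permutations). These used Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3. Shares of signal depend on how strongly each probe binds, so they are not cell numbers.

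The rule for named probes was fixed before the data were examined. It took the probes with the largest differences among those past the threshold, or, where fewer than 5 of a direction passed, those with the smallest p, said not to pass. It also took the leading 16S and FGA probes of each site, the brightest members of a tested list and the probes with the largest mean share. Because the files give no gene names for these probes, at most 2 probes per direction are printed for a comparison. Runs of probes on neighbouring source records (record numbers no more than 10 apart, at least 7 probes) were defined after the data were seen.

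Scan dates fell on 7 days, numbered here in order. Yingshankang arrays were scanned on days 5, 6 and 7 only, and days 5 and 6 held both locations. Arrays of a site were never scanned on the same day. Day 5 had 2 scan sessions: the later held 3 of its 4 Dexing arrays (sites 1, 2 and 5), and the earlier held the array of site 4 and both Yingshankang arrays. Comparisons of locations were therefore repeated with scan day or scan session in the fit, and within days 5 and 6. No 2 arrays had identical values, and the highest correlation of log2 values between any pair of arrays over the 282 tested probes was 0.892, within site 6. The limma tests, camera, fry and the other permutation tests were tried on simulated data with and without a difference, the Mantel test on a matrix against itself and the test of distances within and between sites on separate clusters alone. With 40 of 282 simulated probes changed, limma recovered 52.0% of 2-fold and 95.8% of 4-fold differences between locations. In the test between sites it recovered 11.9% and 86.3% of those at 1 site. Simulated probes varied independently, while the real FGA probes had an estimated correlation of 0.216. The changes were added to values already normalized, so these rates need not hold for real probes near background. Alternatives covered background correction, normalization, the filter on dim probes, spot median against mean, detection limits, the distance, scan day, scan session, and leaving out each site or array.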

Results

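The data describe the microbial DNA in acid mine drainage at 9 sites, 6 at Dexing (sites 1 to 6) and 3 at Yingshankang (sites 7 to 9), with 2 to 4 arrays per site and 23 arrays in all. The series asks how the composition and functional makeup of these communities differ between places. Signal was sparse. Between 1.54% and 18.6% of the 4480 probe spots of an array reached a signal-to-noise value of 2. Of 1120 probes, 405 were detected on 1 or more arrays and 715 on none, and 368 were called at 1 or more sites. These comprised 264 of the 470 FGA probes and 71 of the 524 16S probes. Sites differed most in FGA probes: 169 were called at site 1 and 202 at site 2, against 13 at site 4 and 14 at site 7. The sites called between 6 (site 4) and 36 (site 9) 16S probes. Array 1 of site 4 detected only 19 probes in all, 1 of them 16S, which lowers the calls of that site.

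**Figure D1:**
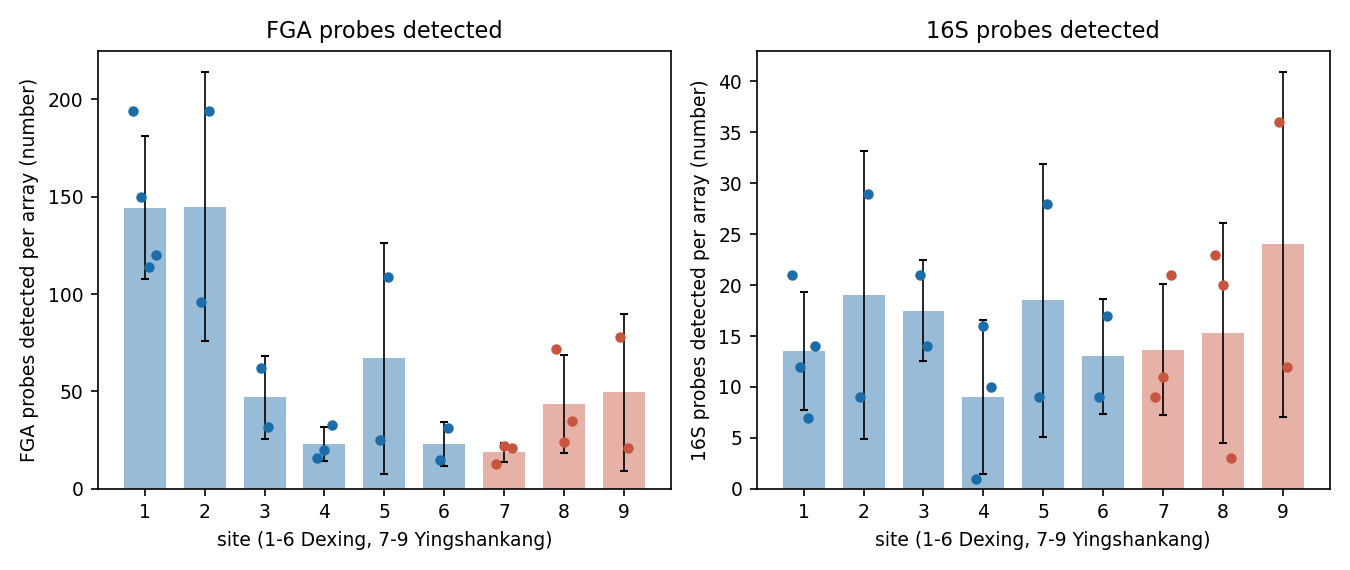
Number of FGA probes (left) and 16S probes (right) detected per array at each site. Bars are site means, points are single arrays, error bars are SD over the 2 to 4 arrays of a site, and blue and red mark Dexing and Yingshankang. The 6 arrays of sites 1 and 2 detected between 96 and 194 FGA probes, while their 16S counts lay among those of the other sites.

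A small set of probes carried signal at every place sampled. Of all probes, 15 were called at all 9 sites and 5 were detected on all 23 arrays. These 5 were the FGA probes FGA275 AB013379.1, FGA183 M58480.1 and FGA168 AF246321.1, the 16S probe 16S AY956336.1, and the probe F10.SEQ F10. FGA275 held the largest mean share of the detected signal, 3.23% ± 1.94 (SD, n = 9 sites), followed by FGA183 with 3.04% ± 1.54. At Dexing alone the order turned, with 2.87% for FGA183 and 2.54% for FGA275, against 3.38% and 4.62% at Yingshankang. Among 16S probes, 16S AY956336.1 led with 2.50% ± 1.80 and reached 6.61% at site 6, and 16S AY635575.1 followed with 2.16% ± 1.92. Their means were 2.50% and 2.52% at Dexing, and 2.50% and 1.44% at Yingshankang. Neither 16S share differed between the locations (exact permutation p = 1 and 0.464, n = 6 and 3 sites). FGA101 AF246306.1, with a mean share of 1.57% ± 3.41, owed it to 10.6% at site 9, where its share was 19.1% on 1 array and 2.03% on the other, and where the site share was 2.83% with the spot median. FGA42 AF246307.1 had a mean share of 1.71% ± 0.904 and was detected on 22 arrays. The remaining 16S probes of the leading 5 were 16S AJ517908.1 (1.63% ± 1.43), 16S AJ517887.1 (1.39% ± 2.37) and 16S AY882664.3 (1.01% ± 1.87). Single sites carried much of the last 2, with 6.41% at site 7 and 5.84% at site 5.

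The heterogeneity between sites was tested over all 23 arrays. Of 282 tested probes, 149 differed between the 9 sites at an adjusted p under 0.05 (limma F-test), comprising 114 of 216 tested FGA probes, 19 of 39 tested 16S probes and 16 of the 27 tested probes with GR or other names. Against the mean of the other 8 sites, adjusted within each site alone, site 1 stood out with 108 probes higher and 37 lower. Of the 108, 104 were FGA probes. At site 2, 63 probes were higher, 59 of them FGA, and 12 were lower. The sites from 3 to 9 each had between 0 and 11 higher probes, with none at sites 4, 8 and 9. Sites 1 and 2 were singled out after the data were seen. The splits at single sites moved with the scaling of the arrays: with a common median site 1 had 153 higher and 7 lower and site 2 117 and 0. With scaling to summed signal site 1 had 76 and 41, site 2 had 3 and 0, and site 4 had 57 and 0. Without site 1, 53 probes differed between the other 8 sites, and without both sites 1 and 2, 9 probes differed between the other 7. Without array 1 of each site 46 passed, and without array 2 of each site 73. Adjusted over the list alone, 19 16S probes passed. With scan day in the fit 150 probes passed, 134 of them among the 149, and with scan session 127 passed. The filter of 2 detecting sites admits probes seen at sites 1 and 2 alone, and among the 58 probes detected at 5 or more sites 16 passed.

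Probes that led at single sites were of both classes. The adjusted p of such a probe covers the 282 tested probes of that site, not the 9 sites together. Most arrays of the other sites did not detect these probes, so undetected arrays there were set to no less than the lowest detected signal of the array. Each fold is then a lower bound of the estimate where every array of the leading site detected the probe. Undetecting arrays of the leading site entered at their own values, and such folds are given without a bound. FGA409 NC_005023.1 was at least 2.77-fold higher at site 1 (adjusted p = 2.95e-06 from limma) and at least 2.62-fold at site 2 (adjusted p = 0.000368). Of the 19 arrays of sites other than 1, 3 detected it. The 16S probe 16S AJ621559.1 was higher at both, at least 2.27-fold at site 1 (limma adjusted p = 0.0366) and 3.64-fold at site 2 (adjusted p = 0.0445), although its F-test over all sites did not pass (limma adjusted p = 0.0829). At site 3, FGA169 AY204368.1, detected on 1 of the 2 arrays and on 3 of the 21 others, was 2.32-fold higher (limma adjusted p = 0.000219) and 16S AJ237904.1 at least 1.64-fold (limma adjusted p = 0.000259). At site 5, 16S AJ517859.1 was the single probe to rise, at least 2.08-fold (limma adjusted p = 0.0414). Site 5 had 1 higher probe with background subtracted, and 0 with a common median, summed signal, no normalization or no background correction. Site 6 had 11 higher probes, 6 of them 16S, led by 16S AF047645.1 at no less than 2.67-fold (limma adjusted p = 0.0112). The count of higher probes at site 6 was 14 without background correction, 3 with background subtracted, and 0 with a common median, summed signal or no normalization. At site 3 it was between 0 (summed signal) and 7, and at site 7 between 0 (summed signal or no normalization) and 2. Among the FGA probes of site 6, FGA494 AB017350.1 was 2.17-fold higher (limma adjusted p = 0.0331), detected on 1 of the 2 arrays. At site 7, 16S AY789589.1 was 1.58-fold higher (limma adjusted p = 0.00445), detected on 2 of 3 arrays and on 2 of the 20 others.

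Probes designed on neighbouring or shared source records were detected together at sites 1 and 2. This grouping was made after the data were seen, and the files give no genes or organisms for it. The longest run, 128 FGA probes on records AF246306 to AF246444, had 104 probes called at site 1 and 113 at site 2. It had 54 at site 5, 41 at site 9, 36 at site 3, and between 7 and 14 at sites 4, 6, 7 and 8. Of 7 probes on record NC_005023, 6 were called at site 1 and 6 at site 2, against 0 to 3 elsewhere. Record AB206839 had 6 and 8 of its 8 probes called at sites 1 and 2 and at most 1 elsewhere, and AF220499 had 5 and 6 of 7 against at most 2. Other runs did not share this. Of 11 probes on records AY204435 to AY204453, 8 were called at site 2, 4 at site 3 and 0 at site 1, and of 17 probes on record AJ320523 at most 3 were called at any site. None of the 12 probes on record AJ345004 was called at any site.

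Mean log2 intensity of the longest run was 7.75 ± 0.05 (SD, n = 4 arrays) at site 1 and 7.66 ± 0.09 (n = 2) at site 2, and at most 7.27 at the other sites. Sites explained 96.2% of the variance of this mean among arrays (permutation p = 1.0e-05, the smallest the permutations can give, adjusted p = 1.0e-04 over 10 runs). Of the 10 runs, 8 differed between sites by this permutation test at an adjusted p under 0.05, but not all in the same direction. AB005218 to AB005222 (6.73 and 6.77) and AJ320523 (6.42 and 6.42) had their lowest means at sites 1 and 2. AJ517851 to AJ517908 had its lowest at site 1 (6.33). These low means are given with quantile normalization only, and other scalings were not tried for these 3 runs. The number of single probes lower at site 1 was 37 with it, 7 with a common median and 2 with no normalization. In AJ320523 only 5 of 17 probes were called at 1 or more sites, and in AJ517851 to AJ517908 only 6 of 35. For AF220499, AJ006456, NC_005023 and the longest run, sites 1 and 2 had the highest means with every scaling except scaling of arrays to their summed signal. With that scaling another site exceeded both sites 1 and 2 in the longest run (7.89 and 7.79 against 7.96). The lower of the 2 was 0.17 below it on the log2 scale. The same held in AJ006456 (7.44 and 7.42 against 7.66). In NC_005023 and AF220499 site 1 lay below the highest other site, and site 2 did not. None of the 10 runs differed between Dexing and Yingshankang, with exact permutation p between 0.0952 and 0.952 (n = 6 and 3 sites).

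**Figure D2:**
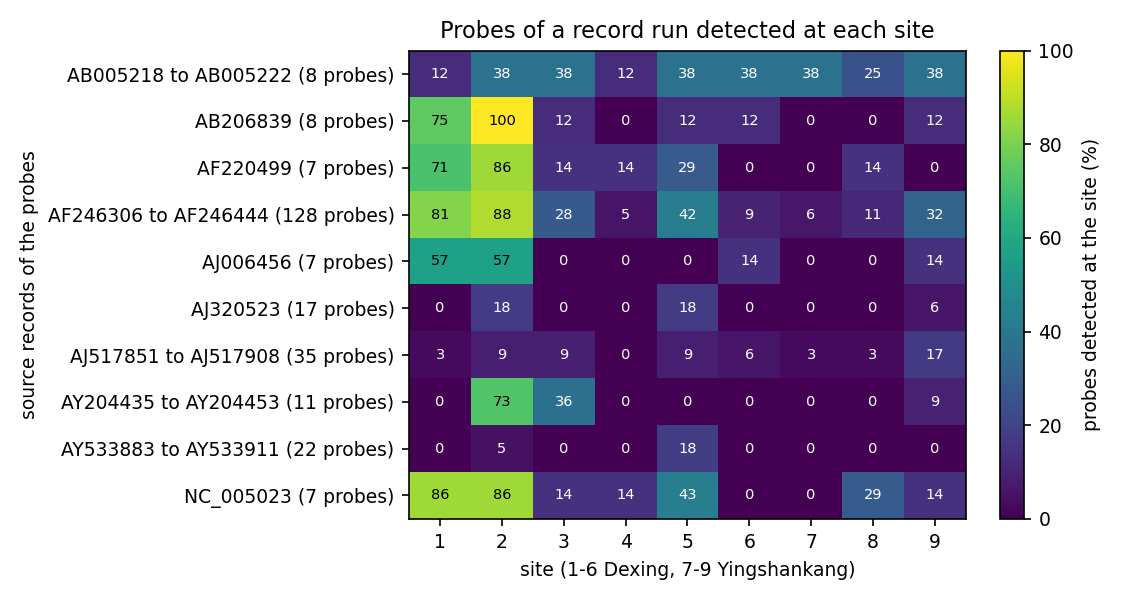
Share of the probes of each record run that was called as detected at each site, in percent, for the 10 runs with at least 5 called probes. Rows are runs of probes on shared or neighbouring source records, columns are sites 1 to 6 (Dexing) and 7 to 9 (Yingshankang). Sites 1 and 2 called 104 and 113 of the 128 probes of the longest run, and site 7 called 8.

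The locations were compared next, with sites as replicates. No tested probe passed an adjusted p of 0.05 between Dexing and Yingshankang (limma, 6 and 3 sites, smallest adjusted p = 0.341). At an unadjusted p under 0.05, 21 of the 282 probes were counted by limma, 11 higher at Dexing and 10 higher at Yingshankang. The probe with the smallest p was GRFGA33 AF307091.1, called at all sites, with a log2 mean of 9.22 ± 0.82 (SD, n = 6) at Dexing and 7.69 ± 0.09 (n = 3) at Yingshankang. The difference was 1.53 (SE 0.40, limma adjusted p = 0.341), 1.05 with scan day in the fit (limma adjusted p = 0.940), 1.06 with scan session (limma adjusted p = 0.996), 0.82 within scan day 5 and 1.44 within scan day 6. Values within day 5 mix location with scan session, since 3 of its 4 Dexing arrays and neither of its 2 Yingshankang arrays were in the later session. It passed without site 3 (limma adjusted p = 0.0365). The 16S probe 16S AY177759.1 was detected on 4 of 15 Dexing arrays and no Yingshankang array (limma adjusted p = 0.481). With Yingshankang arrays at no less than the lowest detected signal, its estimate was 1.29-fold higher at Dexing. Undetecting Dexing arrays entered at their own values, so this is no lower bound. With scan day in the fit its difference was -0.02, and with scan session -0.03. The 16S probe 16S AY789589.1 was detected on 4 of 8 Yingshankang arrays and no Dexing array (limma adjusted p = 0.341). By the same measure its estimate was 1.10-fold higher at Yingshankang, again no lower bound. 16S AY557176.1 had log2 means of 7.58 ± 0.26 at Dexing and 8.36 ± 0.21 at Yingshankang, with a limma adjusted p of 0.481. These 4 probes did not pass. Scaling arrays to their summed signal gave 52 probes past the threshold, all higher at Dexing, with a median log2 difference over all tested probes of 0.65 against 0.03 with quantile normalization.

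The 16S probes were then tested as a list against the other probes, and passed only where the correlation between probes was preset. With spots not found left out it did not pass there either (limma camera adjusted p = 0.0618). Of 39 tested 16S probes, 10 had a higher mean at Dexing, and the median log2 difference was -0.31 (camera adjusted p = 0.000212 at the preset correlation of 0.01). With an estimated correlation of 0.0994 between probes the adjusted p was 0.0742 (camera in limma). Tested by fry against no change, not against other probes, the list was lower at Dexing with a p of 0.102 (limma). With arrays scaled to summed signal the median was 0.23, below the 0.65 of all tested probes. With scan day taken out the camera p from limma at the preset correlation was 0.00156, with scan session 0.0128, and the median 16S difference was -0.19 within scan day 5 and -0.21 within scan day 6. No single 16S probe passed by limma, nor did any adjusted over the list alone (smallest adjusted p = 0.0943), and 5 of 39 had an unadjusted p under 0.05. The brightest 2 members were 16S AY956336.1, with log2 means of 9.27 ± 0.88 at Dexing and 9.57 ± 0.35 at Yingshankang, and 16S AY635575.1, with 9.06 ± 1.02 and 8.84 ± 0.34. The FGA probes as a list, a test added after the data were seen, had a median log2 difference of 0.08 (camera adjusted p = 0.00385 at the preset correlation). That adjusted p was 0.723 with an estimated correlation (limma). Camera sets either list against the other tested probes, and 216 of the 282 tested were FGA. The filter admits FGA probes detected at sites 1 and 2 alone, both at Dexing. It can therefore favour FGA over 16S probes at Dexing in both list tests.

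Diversity was then compared between the locations. Dexing sites had a mean of 102 ± 60.0 detected probes per array (SD, n = 6 sites) and Yingshankang sites 64.8 ± 22.2 (n = 3), a difference of 37.3 that lay within the spread between sites (exact permutation p = 0.357). With scan day in the fit the difference was 55.2 (exact permutation p = 0.202). With scan session in the fit it was 20.5 (exact permutation p = 0.512). Without single sites it ran from 21.9 to 50.1, and the lowest other alternative gave 13.7. Within scan days 5 and 6 it was 123 and 34.0 (exact permutation p = 0.2 and 0.6). The arrays of these days allow only 15 and 10 splits, too few for a p under 0.05. Within the earlier session of day 5 the difference was 1.50, with 49 detected probes on the Dexing array (site 4) and a mean of 47.5 on the 2 Yingshankang arrays. The later session held the Dexing arrays of sites 1, 2 and 5 alone. The Shannon index was 4.20 ± 0.674 at Dexing and 3.47 ± 0.432 at Yingshankang (exact permutation p = 0.143). It was highest at sites 1 (4.97) and 2 (5.00) and lowest at site 7 (2.99). Its difference was 0.731, 0.663 with scan day and 0.580 with scan session in the fit, 1.10 and 0.761 within days 5 and 6, and -0.138 within the earlier session of day 5.

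Pielou evenness, which measures how equally signal spreads over the detected probes, was 0.956 ± 0.0293 at Dexing and 0.854 ± 0.0676 at Yingshankang (exact permutation p = 0.0238). Adjusted over the 3 measures of diversity the p was 0.0714. Without site 7 or without site 9 the exact permutation p was 0.0714, but fewer splits of the sites remain, which raises the smallest possible p. Leaving out single sites gave differences of 0.0794 to 0.141. Evenness was 0.809 at site 7, 0.821 at site 9 and 0.932 at site 8, and 0.898 at site 3, the lowest Dexing site. The difference of 0.102 was 0.0384 with scan day in the fit (exact permutation p = 0.226) and 0.0463 with scan session (exact permutation p = 0.119). It was 0.00363 within day 5, -0.0455 within its earlier session and 0.0800 within day 6. With the spot median in place of the spot mean it was 0.0313 (exact permutation p = 0.226).

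The share of detected signal from 16S probes was 19.2% ± 10.8 (SD, n = 6 sites) at Dexing and 26.5% ± 4.54 (n = 3) at Yingshankang. It ranged from 6.19% at site 1 to 33.4% at site 6. FGA probes held 66.0% ± 17.6 and 60.2% ± 4.34, and probes with GR or other names 14.8% ± 6.90 and 13.3% ± 5.29. None of the 3 shares differed between the locations by an exact permutation test (p = 0.357, 0.607 and 0.738, adjusted p = 0.738 for each). The 16S difference was -7.35 percentage points, -10.8 with scan day and -16.0 with scan session in the fit, -9.63 and -22.3 within days 5 and 6, and -11.9 within the earlier session of day 5. For FGA probes it was 5.86, 12.5 with scan day, 18.7 with scan session, 16.2 and 26.5 within days 5 and 6, and 18.3 within the earlier session. For GR or other names it was 1.49, -1.74 with scan day, -2.73 with scan session, -6.62 and -4.29 within days 5 and 6, and -6.41 within the earlier session. Without single sites the 16S difference ran from -10.2 to -4.75 and the FGA difference from 1.49 to 10.3.

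Of the 368 probes called at any site, 134 were called at both locations, 36.4% (95% Wilson interval 31.7 to 41.4), with 214 at Dexing alone and 20 at Yingshankang alone. The interval treats probes as independent and leaves out the spread between sites. FGA probes made up 169 of the 214, and 16S probes made up 12 of the 20. With 3 Dexing sites drawn to match the 3 Yingshankang sites, the mean over all 20 sets was 116 shared probes, 156 at Dexing alone and 38.2 at Yingshankang alone, a shared share of 37.9% (30.8% to 49.4%). Site 9 alone supplied 87 of the Yingshankang probes, and without it the shared share was 17.6%. It has 2 arrays against 3 at sites 7 and 8, so 1 detecting array was enough for a call there. The drawn sets match the number of sites, not of arrays.

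Community profiles were compared by location and by site. Location accounted for an R2 of 0.157 of the squared Bray-Curtis distances between sites (exact permutation p = 0.190, n = 6 and 3), and for 0.327 and 0.206 of those between the arrays of scan days 5 and 6 (exact permutation p = 0.133 and 0.9). The arrays of these days allow only 15 and 10 splits, too few for a p under 0.05. The nearest other array was of the same location for 17 of the 23 arrays, of the same site for 7 and of the same scan day for 6, where 12.1, 1.82 and 3.18 are expected with no structure. Arrays of the same site had a mean Bray-Curtis distance of 0.584 (20 pairs) and arrays of different sites 0.734 (233 pairs), a difference of 0.149 (permutation p = 6.0e-05). With sites permuted only within scan days the permutation p was 0.0004. With scan days permuted within sites, arrays of different days lay farther apart than those of the same day by 0.00628 (permutation p = 0.0152), a sign of scan day in the distances. Over pairs of different sites with arrays permuted, different days lay farther apart by 0.0203, which did not pass (permutation p = 0.192). The difference between and within sites was 0.186 among Dexing arrays (permutation p = 0.00188) and 0.0459 among Yingshankang arrays (permutation p = 0.0645). Whether these 2 differ was not tested. Without sites 1 and 2 it was 0.0143 (permutation p = 0.247). With 16S probes alone it was 0.0456 (permutation p = 0.0573), and with FGA probes alone 0.165 (permutation p = 1.1e-04). Sites 1 and 2 were the closest pair of sites at 0.255, the next being sites 3 and 5 at 0.469, and sites 1 and 7 the farthest at 0.821.

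Distances between sites from 16S probes were set against those from FGA probes. Over the 36 pairs of sites Pearson's r was 0.243 (Mantel permutation p = 0.0859) and Spearman's rho 0.0839 (permutation p = 0.327). Without sites 5 and 9, the 2 farthest from the median in 16S distance, r was 0.560 (permutation p = 0.0426) and rho 0.421 (permutation p = 0.0671). Without site 2 r was -0.0493 (permutation p = 0.561), and without site 7 or site 9 it was 0.406 or 0.392 (permutation p = 0.0380 and 0.0420).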

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

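All explanations below were weighed with tests chosen after the results were seen, except the test of sites 1 and 2 for the same DNA. Chance marks about 1 in 20 groups of values by the measure used here for a lone value, and 1 of the 22 groups looked at was marked. Pielou evenness at site 3 was 0.898, apart from the other 5 Dexing sites, which lay between 0.959 and 0.978. The control spots, which no comparison used and whose content the labels do not give, carried signal. On the array with the fewest, 24.2% of the 128 control spots reached a signal-to-noise value of 2, and on the array with the most 56.3%, against the 2.34% that a count of 0 allows. Nothing says that control spots should be empty, so this shows only that they gave signal.

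FGA probes were detected most often at sites 1 and 2, and the tables argue against scan day or session as the whole source: on 5 of the 5 scan days with arrays of these sites and of others, each of their arrays detected more FGA probes than each array of another site. Brighter arrays overall would raise 16S detection too, which the tables argue against for site 1 (13.5 16S probes per array), as 5 of the other 7 sites detected as many. For site 2 (19.0) only 1 did. Its 2 arrays detected 9 16S probes against 9 to 14 on arrays of sites 3 to 9 in the same session, and 29 against 28. Their FGA probes numbered 96 against 25 to 32, and 194 against 109. This argues against brighter arrays but rests on 2 arrays and leaves them open. Laser power was not matched in all these contrasts, and its part was not tested. On day 4 it was 3.83 for site 2 against 3.08 for site 3 and 1.79 for site 5. On day 1 it was 3.81 for site 1 against 3.38 for site 6. All arrays of days 2, 5 and 6 lay between 3.72 and 3.85. With summed-signal scaling another site exceeded both in the longest run (7.89 at site 1 and 7.79 at site 2 against 7.96 on the log2 scale). The same DNA on arrays of both sites, through a mix-up or a shared stream, could not be excluded: 2.48% of tested probes had an unadjusted p under 0.05 between sites 1 and 2, and 0 passed the adjusted threshold (limma). Some calls went the other way: of 11 probes on records AY204435 to AY204453, 0 were called at site 1 and 8 at site 2. That run was picked after the data were seen, so it does not decide. A true likeness of these sites stays open too, untested.

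Evenness was lower at Yingshankang, by 0.102. Bright specks within spots may be part of this, since the spot mean follows a speck more than the spot median does. With the median, evenness at Yingshankang was 0.929 ± 0.0370 and at Dexing 0.960 ± 0.0276, and the difference of 0.0313 (exact permutation p = 0.226, n = 6 and 3) was still above the Dexing SD, so specks could not be settled as the whole source. The leading probe of site 9, FGA101 AF246306.1, held 10.6% of the signal with the mean and 2.83% with the median, that of site 8 6.47% and 1.98%, and that of site 4 at Dexing 5.95% and 0.727%, while that of site 7, FGA527 D90110.3, held 10.4% and 11.1%, from 1 of its 3 arrays. Scan day cannot be told apart from location either, as the largest within-day difference was 0.0800 on day 6 and that on day 5 was 0.00363, and -0.0455 within its earlier session.

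For the 149 probes that differed between the 9 sites, 1 of 100 regroupings of the arrays, the real one, gave as many and the highest other gave 20. This argues against chance as the source of the whole count, given the spread between arrays. The tested probes were picked with the real sites, which favours the real grouping, and without sites 1 and 2 only 9 probes differed. The comparison of locations gave 0 probes past the threshold (limma, 21 at an unadjusted p under 0.05), and 84 of the 84 splits of the 9 sites gave at least as many, which a count of 0 fixes beforehand and which therefore tells nothing. For the 21, 13 of the 84 splits gave as many and the highest other gave 133, so chance cannot be excluded. The highest other split past the threshold, sites 1, 2 and 5 against the rest, called 76 probes. It was picked as the highest of 84 and holds sites 1 and 2, so it restates the structure described above and is no separate test. Each of these 3 sites had 1 array in the late session of scan day 5, and without those 3 arrays the same split called 87 probes, 66 of them shared. The lower 16S list at Dexing had a camera p of 0.000212, and 28 of the 84 splits gave one as small, down to 8.89e-08, so chance cannot be excluded as its source.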

How the results depend on the processing

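Alternatives with spots not found left out, with scan day in the diversity fits, with scan session, without array 2 of site 9, without the late session, without sites 1 and 2, and without single sites in the test between sites were chosen after seeing the data, as was the spot median for community measures. Of 247 alternative values of 13 results, 214 were labelled the same. For tests this means the same direction and side of the threshold, so a test that stayed short of it counts. For counts of probes it means a count of similar size. For the shared share it means a change no larger than the distance to the nearer end of its Wilson interval. Few spots above background limit all of them.

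No probe passed between locations except with summed-signal scaling (52, by a shift of all probes) and without site 3 (leaving out single sites gave 0 to 1). The camera p for 16S probes was 0.0742 with an estimated correlation and 0.0618 with spots not found left out. The 149 probes between sites became 16 of 58 tested where detection at 5 sites was required and 9 without sites 1 and 2. Leaving out single sites or array numbers gave 46 to 163, the lowest without array 1 of each site, where several sites keep 1 array assumed to vary like the others. Without array 2 of each site 73 passed.

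The evenness difference was 0.0313 with the spot median, 0.0384 with scan day and 0.0463 with scan session in the fit. Leaving out single sites gave 0.0794 to 0.141, and without site 7 or 9 the exact permutation p was 0.0714, over fewer splits. The shared share of probes was 31.4% at a signal-to-noise limit of 3, 24.1% with 3 of 4 spots, and 17.6% to 37.4% without single sites. The difference in distance between and within sites was 0.0456 with 16S probes and 0.0143 without sites 1 and 2.

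The Mantel correlation passed the threshold at a limit of 3 (r = 0.421), with 3 of 4 spots (0.458), 1 of 4 spots (0.400), the spot median (0.422) and without array 2 of site 9 (0.310). Without single sites it ran from -0.0493 to 0.418. The difference in signal share of GR or other names changed sign with normalized intensity (-0.949), the spot median (-0.208) scan day (-1.74) and scan session in the fit (-2.73), and ran from -0.582 to 4.47 without single sites. For 16S AY177759.1 the difference was -0.0190 with scan day and -0.0336 with scan session as a block. The cause was not tested for any of these but those stated. No paired analysis was possible because the locations share no site number.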

Other observations

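The test in the next paragraph was chosen before its result was seen, its reading by share of detected values after, and the rest are values without a test. Detection differed in breadth between sites of the same location. At Yingshankang, site 9 called 136 probes, site 8 called 57 and site 7 called 33, and 87, 17 and 1 of these were called at no other Yingshankang site. A call needed 1 of 2 arrays at site 9 but 2 of 3 at sites 7 and 8, so part of this reflects array number. The mean number detected per array was 85.0 at site 9 (129 and 41 on its arrays), 68.3 at site 8 and 41.0 at site 7. At Dexing, site 4 called 24 probes on 3 arrays, with a mean of 38.0 detected per array. Its array 1 detected 19, with 98.2% of probe spots not found and a median foreground of 235 against a background of 237. The signal of site 7 was concentrated, with 37.6% in its leading 5 probes, as was that of site 9 with 38.1%, against 6.77% at site 1 and 7.21% at site 2. The 16S probe 16S AY882664.3 led at site 5 with 5.84% of the signal, from 1 of its 2 arrays, and FGA357 X14818.1 led at site 3 with 9.70%, also from 1 of 2.

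A hypothesis was that the FGA probes on records AF246306 to AF246444 follow 1 source and so vary together. Over all 23 arrays the mean correlation between the 112 tested probes of this run was 0.295, against 0.0454 between the 104 other tested FGA probes, which rests on sites 1 and 2. Over the 17 arrays of the other 7 sites it was 0.0618 against 0.0327. The difference of 0.0291 exceeded that of 93.5% of 10000 shuffles of run membership, short of the 95% set in advance. By the rule set in advance this counts against the hypothesis. Only 15.7% of the values of the run on these arrays were detected, so most of what was correlated was background. That reading was added after the result was seen. With it the hypothesis is left open, though it failed its preset limit.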
